A study of Mus musculus with 2 samples.

How the data were processed

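Cultured mouse vascular smooth muscle cells of 4 conditions were tagged with hashing antibodies, pooled and sequenced as 1 gene expression library with its antibody tag library on the 10x Genomics platform, per the labels' protocols. The values are raw UMI counts per feature and barcode, deposited by the authors as 1 unfiltered matrix written by Cell Ranger 7.1.0, per the file header. Genes and tags stand in the same matrix. The submitters' processing notes also name Seurat, with no version or step. Genome build and annotation are not given in the sources used here, so no coordinates are printed, and gene symbols and identifiers are those paired in the feature table. Where 2 identifiers share a symbol, the one with more UMIs was used.

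The labels describe 2 samples, the gene expression library and the tag library. Tags are named HT1 to HT4 and no source used here ties a tag to a condition. The planned comparisons between conditions were not made, the matrix was treated as 1 sample, and no condition was read from the values. Values per tag describe 1 pool of cells each. Cells are not replicates, so no p-value, standard error or count of changed genes was computed from them.

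Droplets were called as cells at the larger of 500 UMIs and a fraction of 0.1 of the 99th percentile of the 3000 barcodes with most UMIs, which gave 6759. Cells had at least 500 genes and at most 15% mitochondrial UMIs. Tags were assigned with HTODemux of Seurat 5.3.0 in R 4.3.3 on centred log ratios, at a positive quantile of 0.99, and droplets with more than 1 tag were left out. Droplets with no tag were kept. Scrublet, run in scanpy 1.11.5 at an expected rate of 0.05, marked 0 of 22725 droplets and so did not work on this library. Its score separated droplets with more than 1 tag from those with 1 tag with an area under the curve of 0.744. Pairs of cells with the same tag are not seen by the tags, and 954 such doublets, 7.45% of the cells with 1 tag, are expected among the kept cells. Pairs that include a cell with no tag over its threshold are not counted in that number, so more doublets may remain.

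Counts were scaled to 10000 per cell and log transformed. After leaving out mitochondrial genes, ribosomal protein genes and all genes of the fixed lists, 2000 highly variable genes and 30 principal components were used. A graph of 15 nearest neighbours with Jaccard weights was clustered by the Leiden method in igraph 0.11.9 at resolution 0.5. Genes that correlate with the lists stayed in, so the clusters are not independent of the cell cycle.

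Levels are UMI sums scaled to CPM with exact Poisson intervals, ratios carry the interval of the exact conditional binomial test, and shares carry exact Clopper-Pearson intervals, all at 95%, computed with scipy 1.17.1. Against 0 counts, a ratio was computed against a floor of 3 counts over the cluster. For each list the median log2 ratio of a cluster to all other kept cells, with a pseudocount of 0.5 UMIs, was placed among 10000 random lists matched in 50 bins of total UMIs. Genes with under 100 UMIs were left out of that step and of the counts of members at least 1.5-fold higher or lower, which are by size with no test. For shares of cells with a UMI, each cell was thinned to 10007 UMIs, the 10th percentile, which left out 2000 cells.

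The 18 gene lists and 13 marker lists and the rule for named genes were fixed before the data were examined, as were the cell filters, tag quantile and cluster resolution. Named are Piezo1 and the other mechanosensitive channels, the 3 members of each list with most UMIs and those with the widest and narrowest ratio between clusters, the 5 genes that lead each cluster, and the 10 most abundant genes. Some of these genes are not reported here. The limits of 100 UMIs per gene and 300 cells per cluster in the ratios, the weights of the graph, the bins, the range of empty droplets and the free RNA share by the cycling rule were set afterwards. In the interferon list 21 of 23 symbols were matched, and in every other list all were.

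The interval and list computations were tested on simulated Poisson counts for cluster 2 against the other kept cells. The intervals assume the same counting error, so this checks the computation and not variation between cells. For 50 genes at 2-fold, 100% of the intervals held the true ratio, for 50 genes at 1.5-fold 98%, for 50 genes at 4-fold 98%, for 50 genes at 0.5-fold 92%, and for 2000 unchanged genes 94.8%. Of 40 unchanged lists, 87.5% fell between the 5th and the 95th percentile. Alternatives were other UMI minimums, mitochondrial limits and doublet handling, other tag thresholds, other cluster resolutions and gene selections, removal of free RNA, and no thinning.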

Results

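The series measured gene expression in cultured vascular smooth muscle cells of C57BL/6 mice by droplet-based single-cell RNA sequencing. Per the labels, 4 cultures were made. They came from young mice of 12 weeks, from old mice of 58 to 78 weeks, from young mice with angiotensin II at 1e-07 M for 48 hours, and from old mice with an siRNA against Piezo1 at 20 nM. Each culture was stained with antibodies that carry an oligonucleotide tag, and the cultures were then mixed and loaded as 1 library, so that the tag counts tell the cultures apart. The matrix held 3477767 barcodes with 559189542 gene UMIs and 10839619 tag UMIs over 32285 genes and 4 tags, named HT1 to HT4. No tag name carries a condition. The comparisons of old with young cells, of angiotensin II with none and of Piezo1 siRNA with none were therefore not made. Each tag's cells are given below as a pool of cells from 1 unnamed culture, with no replicate. All intervals are 95% intervals and cover counting error only.

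At a minimum of 6759 UMIs, 22733 barcodes were called as cells, and 22725 of them passed the filters on genes and mitochondrial UMIs. A further 2722 carried more than 1 tag and were left out, so that 20003 cells were kept. The kept cells held 402850822 UMIs, with a median of 17753 UMIs and 4512 genes per cell. Exactly 1 tag was called in 56.4% of the 22725 droplets (exact binomial interval 55.7 to 57.0), and no tag passed its threshold in 31.6% (31.0 to 32.2). The pools held 2760 cells for HT1, 3792 for HT2, 2415 for HT3 and 3848 for HT4, beside 7188 kept cells with no tag. These numbers depend on the tag rule. HTODemux called 12.1% of droplets HT1, 16.7% HT2, 10.6% HT3 and 16.9% HT4, and a rule that asks for 3 times the counts of the next tag called 27.6%, 5.39%, 0.774% and 7.1% in turn. Median UMIs per cell were 22652 for HT1, 17645 for HT2, 22313 for HT3, 18708 for HT4 and 14746 for cells with no tag.

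**Figure D1:**
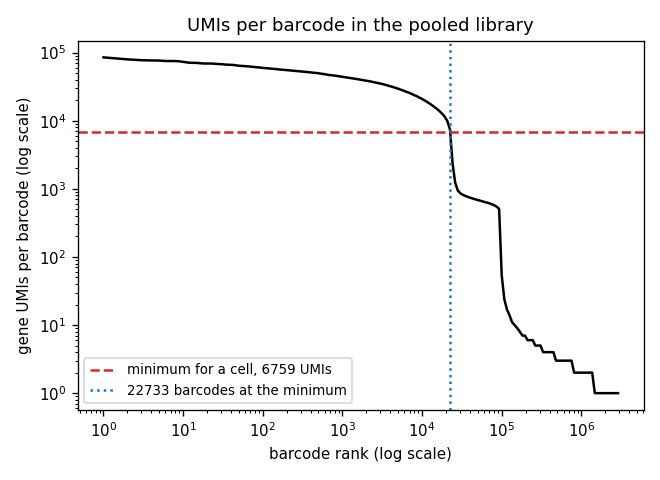
Gene UMIs per barcode against barcode rank in the pooled library, both on log scales, with the minimum for a cell as a dashed line and the number of barcodes that reached it as a dotted line. The curve falls from 22733 barcodes at 6759 or more UMIs to a shelf of 59812 barcodes with 500 to under 800 UMIs.

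Piezo1 (ENSMUSG00000014444), a mechanically gated cation channel and the target of the siRNA, was measured at 65.8 CPM over all kept cells (exact Poisson interval 65.0 to 66.6). Its level was 75.1 CPM in the HT1 pool (73.0 to 77.2), 74.4 CPM in HT2 (72.5 to 76.4), 69.2 CPM in HT3 (67.0 to 71.3) and 47.0 CPM in HT4 (45.5 to 48.5). With every cell thinned to 10007 UMIs, 45.3% of 18003 cells held a Piezo1 UMI (44.6 to 46.0), and 64.1% did so without thinning. The thinned share was 51.2% in HT1, 49.6% in HT2, 46.6% in HT3 and 35.5% in HT4, against unthinned shares of 75.3%, 68.7%, 73.2% and 55.6%. Thinning left out 90, 323, 93 and 294 cells of these pools in turn. No cell type that should lack Piezo1 was identified, so the background was taken from low barcodes. With 633 free UMIs per droplet, the Piezo1 share of barcodes with at most 50 UMIs predicts a UMI in 4.93% of unthinned cells, and that of droplets with 500 to under 800 UMIs predicts 1.21%. The tag names do not state which pool received the siRNA, and it was not read from these values.

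Among the other mechanosensitive channels, Pkd2 (polycystin 2) was the most abundant at 186 CPM, and Trpm7 followed at 81.1 CPM. Piezo2 differed most between clusters. It was measured at 76.1 CPM in cluster 2 and at 1.05 CPM in cluster 8, a ratio of 72.4 (35.1 to 180.2). Its pool levels were 7.79 CPM in HT1, 61.2 CPM in HT2, 9.89 CPM in HT3 and 60.2 CPM in HT4. Tmem63b reached 47.0 CPM, Pkd1 21.9 CPM, Tmem63a 9.95 CPM, Trpc6 9.06 CPM, Kcnk2 6.56 CPM and Tmc6 5.40 CPM. Lower levels were found for Trpm4 with 2.83 CPM, Trpc1 with 1.54 CPM, Trpv2 with 0.876 CPM and Trpv4 with 0.335 CPM. Kcnk4 had 0.0745 CPM, Asic1 0.0745 CPM and Tmem63c 0.0645 CPM. The list summed to 471 CPM. Against all other cells, and among members with at least 100 UMIs, 3 of 15 members were at least 1.5-fold higher and 1 as much lower (percentile 92.7) in cluster 2, where the percentile is that of the list's median log2 ratio among 10000 matched random lists. In cluster 6, 0 of 15 members were at least 1.5-fold higher and 6 as much lower (percentile 68.9). That cluster had the lowest level of the nuclear RNA Malat1, 1912 CPM against 10038 to 16382 CPM in the others, and the fewest genes per cell, with a median of 3593, which bears on every result for it. Piezo1 itself ranged from 49.7 CPM in cluster 5 to 78.5 CPM in cluster 7, a ratio of 1.58 (1.43 to 1.74) among clusters of at least 300 cells.

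**Figure D2:**
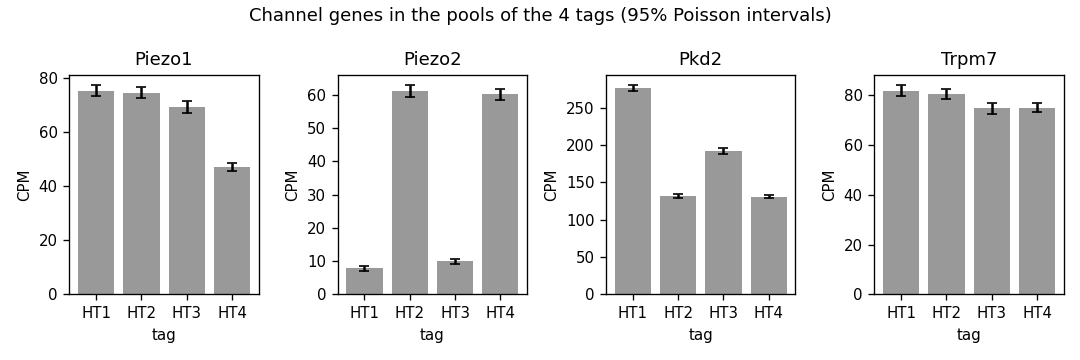
CPM of 4 channel genes in the pools of cells with exactly 1 tag, with 95% Poisson intervals as error bars. Piezo1 lies between 47.0 and 75.1 CPM, and Piezo2 between 7.79 and 61.2 CPM.

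Clustering, run without the genes of the fixed lists, gave 9 clusters, against 8 at resolution 0.3 and 14 at resolution 1. Cluster 1 held 33.2% of the kept cells (32.5 to 33.8), cluster 2 24.5%, cluster 3 14.9%, cluster 4 12.0%, cluster 5 8.16%, cluster 6 3.49%, cluster 7 1.82%, cluster 8 1.70% and cluster 9, with 49 cells, 0.245%. The leading genes, which describe the clusters and are not results, began with Gria1, Slc5a7, Clu, Dpyd and Rspo2 for cluster 1 and with Il11, Fmo2, Dkk2, Npr3 and Klk8 for cluster 2. Cluster 3 was led by Kif14, Esco2, Kif11, Espl1 and Neil3, and cluster 4 by Fbxo5, Ckap2l, Mki67, E2f8 and Pimreg, many of them genes of DNA replication or mitosis. Ror1, Adcyap1r1, Fam20a, Nkain3 and Lpl led cluster 5, and Crct1, Bcl2l15, Fabp3, Cryab and Cd24a led cluster 6. Cluster 7 was led by Upk1b, Wnt4, Sez6l, Plce1 and Stk26, cluster 8 by Trpa1, Gm8126, Sfta3-ps, Gm4951 and Brinp3, and cluster 9 by Rasgrf2, Hfm1, Olfr655, Gm45847 and Rgs6. Of these genes, Kif11, Ckap2l, Mki67, E2f8 and Lpl belong to the fixed lists and took no part in the clustering. The clusters are given by number, since a cluster drawn mostly from 1 pool may be that culture and not a cell type. Cluster 1 held 69.2%, 4.40%, 56.6% and 2.47% of the HT1, HT2, HT3 and HT4 cells in turn. Cluster 2 held 0.652%, 49.7%, 0.952% and 50.1%, and cluster 3 17.1%, 2.69%, 33.5% and 1.79%. Cluster 4 held 0.688%, 19.8%, 0.994% and 23.8%, and cluster 5 0.797%, 12.8%, 3.06% and 17.3%. Among tagged cells, contrasts of clusters 1 and 3 with clusters 2, 4 and 5 are thus largely contrasts between pools.

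Genes of the contractile smooth muscle list were measured in every cluster, at summed levels that varied widely. Their summed level was 2537 CPM over all cells (2532 to 2542), from 954 CPM in cluster 8 to 4962 CPM in cluster 5, a ratio of 5.20 (5.07 to 5.33). Acta2, smooth muscle actin, ranged from 26.7 CPM in cluster 8 to 937 CPM in cluster 5, and Tagln, transgelin, from 47.9 CPM in cluster 8 to 1417 CPM in cluster 7. Cald1, caldesmon, was the most abundant member at 1205 CPM. With Tagln at 502 CPM, Acta2 at 361 CPM and Tpm2 at 360 CPM it made up most of the sum over all cells. Myh11 had 6.55 CPM with a UMI in 4.52% of kept cells, and Cnn1 14.8 CPM with a UMI in 11.5%. Myocd had 0.534 CPM with a UMI in 1.00%. Smtn, smoothelin, varied least with a ratio of 1.77 (1.55 to 2.04), and Des, desmin, varied most, reaching 111 CPM in cluster 7 against 0.901 CPM in cluster 3. The list's median log2 ratio stood at the 100th percentile of 10000 matched random lists in clusters 2 and 5 and at percentile 0 in clusters 1, 3 and 8. In cluster 2, 11 of 15 members were at least 1.5-fold higher and 1 as much lower (percentile 100), and in cluster 8, 1 of 15 members were at least 1.5-fold higher and 13 as much lower (percentile 0).

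Genes of the synthetic smooth muscle state were the more abundant, at 21627 CPM together. Spp1, osteopontin, had 11424 CPM over all cells, from 3679 CPM in cluster 7 to 15015 CPM in cluster 8. Mgp, matrix Gla protein, had 4795 CPM and Thbs1, thrombospondin 1, 1864 CPM. Tnfrsf11b, osteoprotegerin, had the widest range between clusters, with a ratio of 35.7 (9.86 to 295), and Vim, vimentin, the narrowest with 1.72. In cluster 1, 4 of 14 members were at least 1.5-fold higher and 3 as much lower (percentile 15.8), and in cluster 7, 1 of 14 members were at least 1.5-fold higher and 7 as much lower (percentile 0.01). Spp1 and Mgp were also among the 10 genes with most UMIs outside the mitochondrial and ribosomal protein genes. The others were Fth1, Malat1, S100a6, Tmsb4x, Actb, Tpt1, Ccl2 and Eef1a1, and together these genes took 8.77% of all UMIs.

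**Figure D3:**
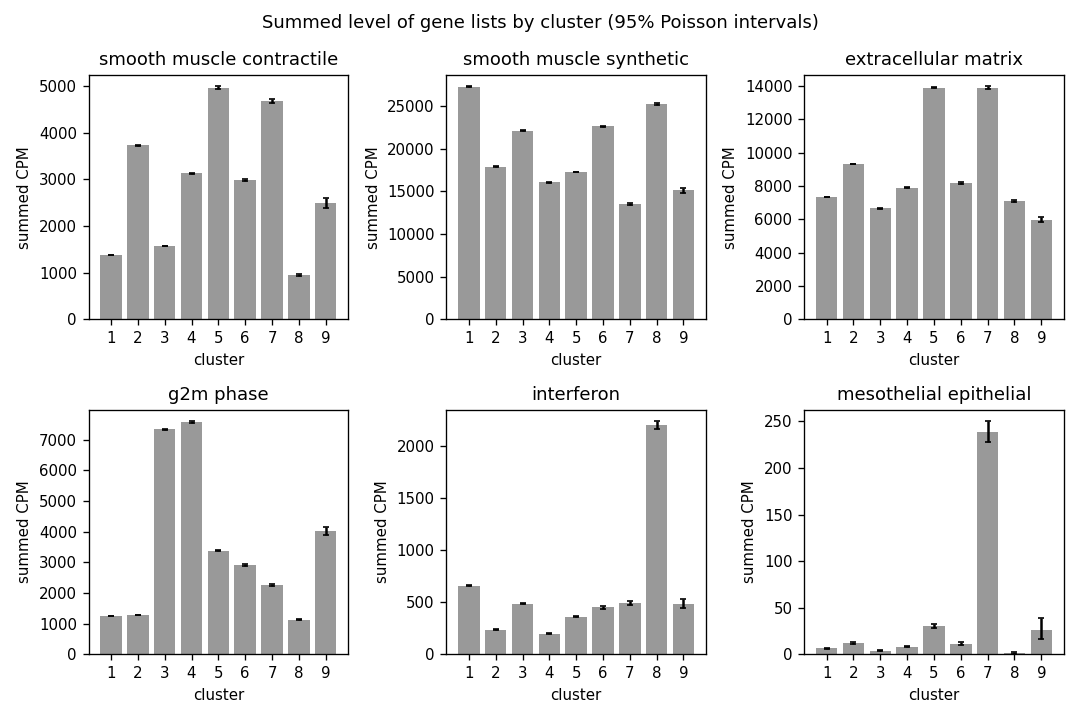
Summed CPM of 6 gene lists in each of the 9 clusters, with 95% Poisson intervals as error bars and a separate linear axis for each list. Contractile genes peak at 4962 CPM in cluster 5, G2/M genes at 7582 CPM in cluster 4, interferon genes at 2199 CPM in cluster 8 and mesothelial or epithelial genes at 239 CPM in cluster 7.

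Extracellular matrix genes summed to 8393 CPM and were highest in cluster 5, at 13903 CPM, and cluster 7, at 13897 CPM. In cluster 7, 13 of 33 members were at least 1.5-fold higher and 9 as much lower (percentile 81.5). In cluster 5, 20 of 33 members were at least 1.5-fold higher and 4 as much lower (percentile 100), and in cluster 3, 0 of 33 members were at least 1.5-fold higher and 16 as much lower (percentile 0). Timp1, an inhibitor of matrix metalloproteinases, had 3368 CPM in cluster 5 against 838 CPM in cluster 1, Tnc, tenascin C, ranged from 219 CPM in cluster 7 to 1452 CPM in cluster 2, and Timp2 had 742 CPM over all cells. Col15a1 had the widest range, with a ratio of 29.5 (11.5 to 109), and Mmp14 the narrowest, with 1.42. Adhesion and cytoskeleton genes summed to 26800.1 CPM, from 14344 CPM in cluster 8 to 35509 CPM in cluster 6. Most of the sum in cluster 6 was Tmsb4x with 11486 CPM and Actb with 10843 CPM. There, 3 of 31 members were at least 1.5-fold higher and 9 as much lower (percentile 18.6). Tmsb4x, Actb and Pfn1 led this list. Myl9, a myosin light chain, varied most with a ratio of 13.4, and Rhoa least with 1.31. In cluster 8, 0 of 31 members were at least 1.5-fold higher and 13 as much lower (percentile 0).

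Targets of YAP and SRF had 2321 CPM, from 1633 CPM in cluster 6 to 2883 CPM in cluster 5. Ankrd1 ranged from 3.75 CPM in cluster 8 to 270.2 CPM in cluster 5, while Tead1, Ccn1, Crim1 and Lats2 varied by ratios of 2.23, 1.87, 2.11 and 1.48. In cluster 5, 5 of 20 members were at least 1.5-fold higher and 0 as much lower (percentile 99.7), and in cluster 6, 0 of 20 members were at least 1.5-fold higher and 6 as much lower (percentile 40.6). Angiotensin and contraction signalling genes had 1172 CPM, from 536 CPM in cluster 6 to 1409 CPM in cluster 1. In cluster 6, 1 of 29 members were at least 1.5-fold higher and 19 as much lower (percentile 0.05). This is the cluster low in Malat1 and in genes per cell. The angiotensin and contraction list was led by Cacna1c, a voltage-gated calcium channel, with 282 CPM, Prkg1 with 215 CPM and Atp2a2 with 184 CPM. Ednrb, an endothelin receptor, had the widest ratio, 22.2, and Orai1 the narrowest, 1.54.

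Cells counted as cycling made up 51.4% of 18003 cells thinned to 10007 UMIs (50.7 to 52.2), and 62.3% of all kept cells without thinning, where the rule is at least 2 UMIs over 8 mitotic genes. In clusters 3 and 4 the thinned shares were 99.3% and 98.6%, against 28.9% in cluster 1, 26.8% in cluster 2, 50.5% in cluster 5, 69.9% in cluster 6, 30.7% in cluster 7, 27.0% in cluster 8 and 79.5% of 39 cells in cluster 9. By pool, the thinned share was 41.1% in HT1, 47.9% in HT2, 56.5% in HT3 and 52.4% in HT4. G2/M genes summed to 3423 CPM and S phase genes to 1290.3 CPM. In clusters 3 and 4 alike, 50 of 52 G2/M members and all 41 S phase members were at least 1.5-fold higher than in the other cells (percentile 100 for both lists). In cluster 6 the G2/M list ran against that share, since 0 of 52 members were at least 1.5-fold higher and 22 as much lower (percentile 3.12). Hmgb2 with 322 CPM, Cks1b and Tubb4b led the G2/M list, in which Kif11 varied most and Psrc1 least. Pcna with 91.4 CPM, Nasp and Tipin led the S phase list. Free RNA was not subtracted from these shares. At its level in barcodes with at most 50 UMIs it predicts 3.30% of thinned and 9.02% of unthinned cells by this rule, and at that of droplets with 500 to under 800 UMIs 3.87% and 10.5%.

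Inflammatory genes summed to 10795 CPM. Ccl2, a chemokine that attracts monocytes, had 4489 CPM, the siderophore-binding Lcn2 1622 CPM and Saa3 1333 CPM. Lcn2 was highest with 4655 CPM in cluster 8 and Saa3 with 3646 CPM in cluster 7. Cluster 8 had the highest sum, 15734 CPM, but there 3 of 20 members were at least 1.5-fold higher and 9 as much lower (percentile 0.17). Il33 varied most, with a ratio of 48.3, and Nfkbia least with 1.44. In cluster 2, 9 of 20 members were at least 1.5-fold higher and 3 as much lower (percentile 100), and in cluster 3, 1 of 20 members were at least 1.5-fold higher and 11 as much lower (percentile 0). In the senescence and secretory list, at 9923 CPM, Ccl2, Timp1 and Ccnd1 led. Igfbp5 varied most, from 2.90 CPM in cluster 3 to 86.9 CPM in cluster 2, and Trp53 least. In cluster 5, 7 of 23 members were at least 1.5-fold higher and 5 as much lower (percentile 0.11). The median log2 ratio there was small, -0.16, and the summed level of 11256 CPM lay above that over all cells. Interferon genes had 469.6 CPM over all cells and 2199 CPM in cluster 8 (2164 to 2235), where 17 of 20 members were at least 1.5-fold higher and 0 as much lower (percentile 100). Bst2, tetherin, made up most of that sum with 1836 CPM, while Isg15 had 94.3 CPM there. The interferon list also stood at percentile 100 in cluster 1, with 7 members higher and 0 lower, and in cluster 5, with 6 and 3. In cluster 7 it stood at 99.99, with 9 and 5. Ddx58 had 23.6 CPM over all cells, Oas1a varied most and Usp18 least.

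Ferritin and antioxidant genes summed to 30159 CPM, led by Fth1, Mt1 and Ftl1, and in cluster 8, 7 of 20 members were at least 1.5-fold higher and 0 as much lower (percentile 100). Fth1, ferritin heavy chain, ranged from 8781 CPM in cluster 4 to 48769 CPM in cluster 8. Sod3 varied most and Sod1 least. Immediate early and heat shock genes, which respond to dissociation, had 3673 CPM, with Hsp90aa1, Hspe1 and Ier3 leading, Hspb1 at the widest ratio, 7.60, and Junb at the narrowest. In cluster 4, 0 of 20 members were at least 1.5-fold higher and 7 as much lower (percentile 0). Cluster 9, of 49 cells, had 6427 CPM, the highest level of any cluster, and there 12 of 20 members were at least 1.5-fold higher and 2 as much lower (percentile 100), with Atf3 at 185 CPM against 2.24 CPM in the other cells. Endoplasmic reticulum stress genes had 3279 CPM, with Hsp90b1, Calr and Pdia3 leading, Chac1 varying most and Canx least, and at most 3 of 17 members were 1.5-fold lower in any cluster of at least 300 cells. Their median ratio stood at percentile 99.9 in cluster 5 and 99.2 in cluster 2, with 1 and 2 members at least 1.5-fold higher. The lowest percentile was 5.2, in cluster 3, while the lowest median log2 ratio was -0.253, in cluster 6 at percentile 42.4. Glycolytic and hypoxia genes had 6594 CPM, with Gapdh, Ldha and Pkm leading, Egln3 varying most and Pkm least. In cluster 2, 8 of 21 members were at least 1.5-fold higher and 0 as much lower (percentile 100), and in cluster 8, 0 of 21 members were at least 1.5-fold higher and 9 as much lower (percentile 0). The TGF-beta and BMP list had 3647 CPM, with Fst, follistatin, at 1142 CPM, Id3 and Grem1 leading, Bmp2 varying most and Smad4 least. In cluster 7, 5 of 25 members were at least 1.5-fold higher and 9 as much lower (percentile 0.05). Cholesterol synthesis genes had 876 CPM, from 670.3 CPM in cluster 6 to 1029 CPM in cluster 5. In cluster 6, 0 of 17 members were at least 1.5-fold higher and 5 as much lower (percentile 39.8). The percentile was 99.98 in cluster 5, with 1 member as much higher and 0 lower. In cluster 7 it was 0.48, with 0 members higher and 1 lower. Fdps, Idi1 and Msmo1 led them, and Fdft1 varied least with a ratio of 1.29.

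Positional identity genes summed to 566 CPM, led by Hoxa5 with 142 CPM, Gata6 with 91.0 CPM and Twist1 with 59.2 CPM. Gata4 varied most, reaching 20.7 CPM in cluster 7, with a ratio of 69.0 (18.8 to 575) to cluster 8, and Hoxb3 least, from 38.4 CPM in cluster 7 to 57.5 CPM in cluster 2. In cluster 8, 0 of 22 members were at least 1.5-fold higher and 17 as much lower (percentile 0). Sex chromosome genes summed to 445 CPM, led by Xist, the RNA that coats the inactive X chromosome, with 294 CPM, and by the Y-linked Uty with 52.9 CPM and Ddx3y with 45.5 CPM. Xist ranged from 23.3 CPM in cluster 8 to 754 CPM in cluster 4.

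Markers of other cell types were low for blood and endothelial cells. Endothelial markers summed to 14.5 CPM, macrophage markers to 25.1 CPM, of which Cd14 gave 21.2 CPM, lymphocyte markers to 4.45 CPM, erythroid markers to 2.05 CPM and cardiac or skeletal muscle markers to 5.66 CPM. Egfl7 had 9.40 CPM, Tnnc1 4.29 CPM, Ccl5 3.65 CPM, Pecam1 2.69 CPM, Alas2 1.99 CPM and Csf1r 1.52 CPM. Fibroblast markers had 733 CPM, with Dcn, Gsn and Serpinf1 leading and Cd34 highest with 127 CPM in cluster 8. Pericyte markers had 60.7 CPM, most of it Pdgfrb with 41.9 CPM, and Rgs5 varied most. Adipocyte markers had 359 CPM, nearly all of it Fabp4 with 339.6 CPM, and Lpl reached 185 CPM in cluster 7. Schwann or neural markers had 166 CPM, led by Ncam1 with 139 CPM. Chondrocyte or osteoblast markers had 123 CPM, led by Runx2 with 75.8 CPM and Sox9 with 46.8 CPM. Mesothelial or epithelial markers had 13.6 CPM over all cells and 239 CPM in cluster 7 (228 to 250.1), where Wt1 reached 143 CPM and Krt18 60.4 CPM. Only 4 of the 8 members reached 100 UMIs over all kept cells. Of these 4, 3 were at least 1.5-fold higher in cluster 7 and 0 as much lower (percentile 100). Wt1 was not detected in cluster 8. With a floor of 3 counts put in place of 0 over that cluster, the ratio of cluster 7 to it was at least 318. The interval of 108 to 1543 treats that floor as counted UMIs.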

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

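Settings that use only cells with exactly 1 tag, leave out cells over the 90th percentile of UMIs or take free RNA from droplets with 500 to under 800 UMIs were chosen after seeing the data. The 2 alternatives planned for the comparisons between conditions were not run, since no tag is tied to a condition. No paired analysis was possible because no replicate was labelled. The number of kept cells, 20003, became 24331 at a fixed minimum of 1000 UMIs, 28711 at 500 UMIs and 22725 with doublets kept. The share of droplets with exactly 1 tag, 56.4%, became 62.9% at a tag quantile of 0.95 and 40.8% when the leading tag needed 3 times the next. The tag quantile of 0.95 called 14.4% of droplets HT1, 17.4% HT2, 12.7% HT3 and 18.3% HT4. Under the rule of 3 times HT1 rose from 12.1% to 27.6% while HT3 fell from 10.6% to 0.774%, so pool sizes rest on the tag rule. Gene levels by pool were not computed under the other rules. The rule of 3 times takes raw counts and favours HT1, whose background was high. The median HT1 count in cells of other tags was 43. Called cells held medians of 80 HT2, 51 HT3 and 105 HT4 counts. In droplets with 500 to under 800 UMIs the median HT1 count was 40, against 6, 11 and 14 for the other tags in turn. The share of the largest cluster, 33.2%, became 33.9% at resolution 0.3, 15.1% at resolution 1, 31.9% with list genes among the variable genes and 28.7% without genes correlated with the cycling lists. The contractile ratio of 5.20 became 4.99 with doublets kept and 5.82 after subtracting free RNA as in those empty droplets. The cycling share of 51.4% became 62.3% without thinning, 71.2% at 1 UMI, 42.5% at 3 UMIs, 49.4% in cells with exactly 1 tag and 49.3% without cells over the 90th percentile. The share with a Piezo1 UMI, 45.3%, became 64.1% without thinning and 9.42% at a fixed minimum of 1000 UMIs, where cells are thinned to 1596 UMIs in place of 10007. The number of clusters, 9, became 8 at resolution 0.3 and 14 at resolution 1. The kept cells at a limit of 10% mitochondrial UMIs, 19938, stayed within the counting interval, as did the contractile ratio with free RNA scaled by globins or in cells with exactly 1 tag, and the Piezo1 share in cells with exactly 1 tag or without the cells of most UMIs. The globins gave a free RNA share of only 0.429%, from 11 UMIs in kept cells and 39 in barcodes with at most 50 UMIs. Droplets with 500 to under 800 UMIs gave 3.57%. The globin setting could therefore move the ratio little. Otherwise the cause of the moves listed here was not tested.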

Other observations

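All tests in this part were chosen after the results were seen, and Hoxb5 and the values by pool were chosen after they were seen. Cluster 6, with 699 cells, stood apart by its low level of Malat1, a long noncoding RNA of the nucleus. It held 1912 CPM (Poisson interval 1889 to 1935), against 10038 to 16382 CPM in the other clusters. Among clusters of at least 300 cells, Cacna1c was lowest there at 68.0 CPM and Prkg1 at 57.7 CPM. The median was 15059 UMIs and 3593 genes per cell, with 1.81% mitochondrial UMIs. The cluster held 4.13% of the HT1 cells, 3.77% of HT2, 4.02% of HT3 and 3.27% of HT4.

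Several list genes differed between the pools of unnamed cultures. Acta2 was measured at 86.6 CPM in HT1, 561 in HT2, 202 in HT3 and 772 in HT4. Hoxb5, a positional gene of the homeobox family, had 4.82 CPM in HT1, 35.1 in HT2, 4.14 in HT3 and 29.4 in HT4. Bst2 had 758 CPM in HT1, 159 in HT2, 288 in HT3 and 126 in HT4. Contractile genes summed to 1264 CPM in HT1, 3569 in HT2, 2024 in HT3 and 4130.1 in HT4. Cluster 7 held 6.54% of the HT2 cells and at most 0.858% of each other tag's cells. Cluster 8 held 196 of the 2760 HT1 cells and at most 0.455% of each other tag's cells.

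The shared part of the pools' cluster distributions was 80.7% between HT1 and HT3 and 90.9% between HT2 and HT4, but 62.9% and 62.4% at resolution 1 and 70.0% and 78.2% without genes correlated with the cycling lists. It was 13.4% between HT1 and HT2, 10.1% between HT1 and HT4, 16.4% between HT2 and HT3 and 13.0% between HT3 and HT4, and at most 17.0% under any clustering tried. A difference in UMIs per cell predicts that thinning removes this split, but after thinning to 10007 UMIs and clustering again the highest value between these 4 pairs was 16.0%. The sex of the cells predicts that cells with at least 2 Y-linked UMIs and at most 1 Xist UMI mix, but among them the highest was 13.0%. Age and treatment, which the design names, stay open and untested. So do the donor mice and the culture. Each pool is 1 culture with no replicate, so these cannot be told apart. The pools also differ in their shares of cells with Xist, given below.

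Droplets of low RNA content may be part of the 31.6% of called droplets in which no tag passed its threshold. Of these, 24.4% lay below the 10th percentile of UMIs of droplets with 1 tag, between the bounds set for and against it, so this stays open. The cluster distribution of cells with no tag shared 67.5% with HT1 and 73.3% with HT3, against 40.9% with HT2 and 38.0% with HT4, a gap of 26.5 percentage points between the nearest values (23.3 to 29.0 under the other clusterings). Dim staining of HT1 and HT3 is a candidate explanation, and for HT1 so is high background, since droplets with 500 to under 800 UMIs held a median of 40 HT1 counts against 6 for HT2, 11 for HT3 and 14 for HT4. Cells called HT1 held a median of 223 counts of their tag, against 80 for HT2, 51 for HT3 and 105 for HT4. Those medians are set in part by the threshold of each tag, so they do not decide between these explanations. No biological explanation was tested.

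Cells with at least 3 Xist UMIs and no Y-linked UMI made up 0.580% of HT1, 41.9% of HT2, 1.16% of HT3 and 46.8% of HT4. Cells with at least 2 Y-linked UMIs and at most 1 Xist UMI made up 77.9%, 30.1%, 74.7% and 28.3% in turn. Doublets or mixed droplets predict both kinds of UMI in the same droplets. At least 3 of each were held by 6.38% of HT2 cells and 6.44% of HT4 cells. The products of the separate shares give 16.9% and 17.4%. Those products hold if the 2 kinds are independent, and doublets in a part of the droplets would give less. Values under the products therefore do not exclude doublets. In HT1 3.37% held both against a product of 3.81%, and in HT3 2.11% against 3.09%. Droplets with both kinds leave the cells with Xist and no Y-linked UMI unexplained. Free RNA as in droplets with 500 to under 800 UMIs predicts at least 3 Xist UMIs in 2.83e-05% of cells, and barcodes with at most 50 UMIs predict any Xist UMI in 17.1%, against 56.5% with at least 3 observed in HT2 and 60.2% in HT4. A mixture of cells from female and male mice within HT2 and HT4 may be present and remains a hypothesis, since the labels used here give no sex.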
